A study of Homo sapiens with 9 samples.

How the data were processed

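RNA sequencing was performed on H1 cells, an established human embryonic stem cell line grown on matrigel in a feeder-free medium with FGF2 and Activin A. Cells were left untreated or received 50 ng/mL of recombinant BMP4, a ligand of the TGF-beta superfamily, for 1 h or 4 h. Each of the 3 groups has 3 libraries, made from total RNA of cells at consecutive passages, so that the 9 libraries come from repeated cultures of a single line. Samples were grouped by the treatment given in the labels. Per the labels' protocols, libraries were prepared with a standard Illumina procedure, and whether strand was kept is not stated.

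The files used here hold the authors' comparison and no values per library. Per the submitters' processing notes, reads were processed with TopHat2 2.0.9 and Cuffdiff against hg19. The name of the deposited workbook refers to DESeq, whereas the submitters' notes list Cuffdiff, and which of these produced the fold changes is not given in the sources used here. The read counter, its settings and the normalization are not given either. The deposited total count of each gene is a signal summed by the authors over libraries, per the file headers, and none of the 19088 totals is a whole number. The deposited p-values and FDR values compare untreated cells with 1 h and with 4 h of BMP4, per the file headers. The deposited fold change is a signed score without values between -1 and 1, in which a negative sign marks a gene higher after BMP4, as the signs in the authors' lists of higher and lower genes show. It was converted to a log2 fold change of BMP4 over untreated, so that positive values are higher after BMP4.

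The deposited FDR equals the Benjamini-Hochberg value over all 19088 rows at 1 h. At 4 h it equals that value over 17607 rows, because 1481 rows have no FDR there. Those rows are the ones with the lowest totals, up to 26.3 counts. Of the row names, 17662 are gene symbols in the NCBI annotation of GRCh38.p14, and 18506 match a single current symbol when older symbols are included. That annotation was used only for names and for which genes neighbour or overlap each other, and no coordinates are given because the authors' build is hg19. Spreadsheet software had turned 24 names into dates, and those rows are not named here. A set of 55 rows repeats the values of another row, in 26 groups of identical rows.

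Because no values per library were used, the planned count models were replaced by the fallback fixed before the data were examined: the authors' fold change, with a gene called at the authors' FDR under 0.05. For each log2 fold change, a standard error was derived as its size divided by the normal quantile of the authors' two-sided p-value, and is called the implied SE. It assumes a Wald-type test. Across 4523 genes with totals of at least the median and a p-value between 0.2 and 0.9 at both times, the implied SE at 4 h divided by that at 1 h had a median of 0.999 and an SD of 0.00241, which a shared fit of all libraries would give. The 95% intervals are the log2 fold change plus or minus the normal quantile times the implied SE. They reflect the error that the authors' model gave to a fold change between groups. They are not a spread between libraries, and no SD between libraries could be given.

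The change between 4 h and 1 h was described as the difference of both log2 fold changes, without a test, as fixed beforehand. A test of that difference was added after seeing the data. It divides the difference by the root of the summed squares of both implied SEs, which takes the comparisons as independent and is conservative because both use the same untreated libraries. A second version removes the shared part by assuming equal relative spread in all groups. Both were adjusted by Benjamini-Hochberg over 17607 genes. They were tested on simulated data with the deposited totals and implied SEs of 17607 genes. Of these, 200 were changed at 4 h alone by log2 folds of 0.5, 1, 2 or 3. All 200 were drawn from genes with totals of at least 2511 counts, so recovery at lower totals was not tested. The simulated spread was equal in all groups, which is what the second version assumes. It was also taken as known, so the error of estimating spread from few libraries was not simulated. The conservative version recovered 42.0% of genes changed by 0.5, 96.0% of those changed by 1 and 98.0% of those changed by 2, and called 0 unchanged genes. The second version recovered 86.0%, 98.0% and 100% of these and called 15 unchanged genes.

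Lists of genes for 16 pathways, cell types and controls were fixed before the data were examined: BMP-SMAD1/5 targets, primitive streak and mesoderm, definitive endoderm, pluripotency, trophectoderm and amnion, neural ectoderm, WNT signalling, NODAL/Activin signalling, FGF/ERK feedback, Notch/HES, immediate-early response, epithelial-mesenchymal transition, BMP pathway components, stress and p53 response, fibroblast and feeder markers, and housekeeping reference. Some genes stand in more than 1 list. For each list and time, the members among the genes called higher and lower were compared with all genes that have an FDR by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over all 64 tests. The median log2 fold change of a list was also placed among 10000 random lists matched on total counts in 20 bins. Those percentiles describe these libraries and treat genes as independent. They are not matched on the implied SE, which was larger than in matched lists for most lists. Members were also counted with the FDR adjusted over the list alone.

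The rule for named genes was fixed before the data were examined. It takes, per comparison, up to 10 called genes with the largest positive and 10 with the largest negative log2 fold change among those with a total of at least the median of 1936 counts, leaving out small non-coding RNAs. Names that are only LOC numbers or dates were not taken as gene symbols. The rule adds ID1, ID2 and ID3, ACTB and GAPDH, and from each list the called members, except 1 that is not reported individually, and up to 4 members that did not pass. RHOH, DNAAF4-CCPG1, FAM72A, the RGPD genes, RANBP2, RPL30, GATA5 and the neighbouring genes named in the closing part were chosen after their values were seen.

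For the overlap between times, the number expected for independent lists was computed from the calls of each, and 100 simulations drew unchanged groups against shared untreated values. Alternatives were an FDR under 0.01, an absolute log2 fold change of at least 1, no filter on low totals at 4 h, and a list background of genes with totals of at least 2511 counts, the median of genes with an FDR at 4 h. Added after seeing the data were the rule of the authors' lists, an adjustment at 1 h over the genes with an FDR at 4 h, and the removal of repeated rows and RGPD genes. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Sequences shared between RGPD genes were taken from GENCODE release 29 transcripts.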

Results

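The early transcriptional response of human embryonic stem cells to BMP4 was measured by RNA sequencing of H1 cells that were untreated or had received 50 ng/mL of BMP4 for 1 h or 4 h, with 3 libraries per group. The study asked which genes respond first as the cells leave pluripotency towards mesendoderm, the common precursor of mesoderm and endoderm. The authors' deposited table lists 19088 genes with a total count over all libraries, and these totals sum to 196462004 counts. The median gene had 1936 counts, and the mitochondrial ribosomal RNA RNR2 took 14.4% of the sum. The depth of each library is unknown from the files used here. Precision followed the totals, since the median implied SE of a log2 fold change at 4 h was 0.62 in the 25% of genes with the lowest totals and 0.09 in the 25% with the highest. All fold changes, implied SEs and FDR values below come from the authors' deposited table and are given as log2 of BMP4 over untreated ± implied SE. The median log2 fold change over all genes was 0.00 at both times.

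Direct targets of BMP signalling were examined first because they check the treatment labels. ID1, ID2 and ID3, which encode inhibitors of basic helix-loop-helix transcription factors, were higher at both times in the authors' deposited table. ID1 rose 5.04-fold at 1 h (2.33 ± 0.11, FDR = 9.06e-101) and 5.27-fold at 4 h (2.40 ± 0.11, FDR = 1.30e-106). ID3 rose by 1.39 ± 0.13 and 1.58 ± 0.13, with FDR = 7.69e-23 and 3.07e-30. ID2 rose by 1.33 ± 0.25 and 1.13 ± 0.25, with FDR = 9.36e-05 and 0.000527. The reference genes ACTB and GAPDH did not pass at either time, and the 95% interval of the authors' values at 4 h was -0.03 to 0.21 for ACTB and -0.04 to 0.19 for GAPDH.

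After 1 h of BMP4, a small set of genes had changed, and most of them were higher. The largest change among well-expressed genes in the authors' deposited table was that of GATA2, a zinc-finger transcription factor of trophectoderm and blood, which rose 34.2-fold (5.10 ± 0.30, FDR = 7.68e-61). BAMBI, a decoy receptor that dampens BMP and TGF-beta signals, rose by 2.75 ± 0.18 (FDR = 1.25e-50), and SMAD7, an inhibitory SMAD, by 2.03 ± 0.16 (FDR = 2.25e-31). GADD45B, a stress-inducible gene, rose by 2.04 ± 0.25 (FDR = 2.25e-13). HES1, a transcriptional repressor best known as a Notch target, rose by 1.86 ± 0.19 (FDR = 2.73e-18), and SOCS3, a feedback inhibitor of cytokine signalling, by 1.52 ± 0.15 (FDR = 2.78e-20). ID4 rose by 1.30 ± 0.15 (FDR = 2.49e-14). In total 53 genes were called by the authors' FDR under 0.05, of which 47 were higher and 6 lower, and 38 of the higher genes had at least doubled. The lower genes were RHOH (-1.05 ± 0.21, FDR = 0.000472), DNAAF4-CCPG1 (-2.11 ± 0.48, FDR = 0.0054), FAM72A (-0.79 ± 0.21, FDR = 0.0497), NFYA (-0.38 ± 0.10, FDR = 0.0221), ZNF12 (-0.37 ± 0.09, FDR = 0.0365) and C21orf91 (-0.35 ± 0.09, FDR = 0.0249). DNAAF4-CCPG1 is a readthrough transcript that overlaps its parent genes and FAM72A has near-identical copies, so their values are uncertain.

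The called genes at 1 h concentrated in the list of BMP-SMAD1/5 targets, where 9 of 20 members were higher in the authors' deposited table and 0 lower (Fisher's exact test, adjusted p = 1.55e-17). Adjusted over the list alone, 14 members were higher. Besides the genes above, GATA3 rose by 4.40 ± 0.56 and SMAD6 by 1.45 ± 0.27. SMAD9 stood at 0.01 ± 0.28, MSX1 at 2.23 ± 1.30, MSX2 at 2.27 ± 0.76 and ATOH8 at 0.73 ± 0.81, and these did not pass.

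Regulators of early lineages were already among the genes called at 1 h. In the primitive streak and mesoderm list, 4 of 23 members were higher in the authors' deposited table (Fisher's exact test, adjusted p = 4.42e-06), or 7 when adjusted over the list alone. They were the transcription factors HAND1 (3.83 ± 0.62), TBX3 (2.42 ± 0.42), FOXF1 (5.04 ± 1.22) and SNAI1 (1.17 ± 0.29). T stood at 0.13 ± 0.76, EOMES at 1.27 ± 0.37 (FDR = 0.141) and MIXL1 at 1.66 ± 0.93, and these did not pass. In the trophectoderm and amnion list, GATA2, GATA3 and HAND1 were higher, 3 of 17 members (Fisher's exact test, adjusted p = 9.91e-05), and 5 passed when adjusted over the list alone. All 3 also stand in the lists above. Against a background of genes with totals of at least 2511 counts, the median of genes with an FDR at 4 h, 6 members of this list remained and the adjusted p of Fisher's exact test was 0.102. No member of the primitive streak and mesoderm list reached that total, so its calls rest on genes with few counts.

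Some members of the Notch/HES and immediate-early lists were also higher at 1 h in the authors' deposited table. HES1 and the Notch ligand DLL4 (3.19 ± 0.70) were the 2 of 16 Notch/HES members that rose (Fisher's exact test, adjusted p = 0.00495), and 4 passed when adjusted over the list alone. KLF4 (1.18 ± 0.27) and KLF10 (0.99 ± 0.18) were the 2 of 27 immediate-early members that rose (Fisher's exact test, adjusted p = 0.0128), with 6 adjusted over the list alone, while FOS stood at 0.59 ± 0.23, JUN at 0.21 ± 0.12 and FOSL1 at 0.10 ± 0.20. Neither call held against the background of genes above that median, where the adjusted p of Fisher's exact test was 0.108 for Notch/HES and 0.145 for the immediate-early list. FGF4, the only called member of 16 in the FGF/ERK feedback list, rose by 1.92 ± 0.33. DUSP4 stood at 0.02 ± 0.20, DUSP5 at -0.05 ± 0.11, DUSP6 at 0.17 ± 0.14 and SPRY1 at -0.17 ± 0.32, and these did not pass. FZD8, a WNT receptor, rose by 0.62 ± 0.15 as the only called member of the WNT list, and HHEX by 1.71 ± 0.36 as the only called member of the definitive endoderm list. The pluripotency list (KLF4), NODAL/Activin list (SMAD7), epithelial-mesenchymal transition list (SNAI1), BMP pathway components (BAMBI) and stress and p53 list (GADD45B) each had 1 called member as well. Fisher's exact test gave an adjusted p = 0.13 for the endoderm, FGF/ERK, NODAL/Activin, epithelial-mesenchymal and stress lists, 0.154 for the BMP pathway components, 0.161 for WNT and 0.167 for pluripotency. In the neural ectoderm, fibroblast and housekeeping lists, 0 members were called by the authors' FDR at 1 h. At an unadjusted p-value under 0.05 in the authors' deposited table, 2 neural members were higher, 1 fibroblast member was lower and 0 housekeeping members differed.

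After 4 h of BMP4, many more genes had changed. The authors' deposited table gave 499 genes at FDR under 0.05, of which 366 were higher and 133 lower. GATA2 remained 33.6-fold higher (5.07 ± 0.30, FDR = 2.01e-60) and BAMBI was 11.1-fold higher (3.47 ± 0.18, FDR = 5.59e-82). NOG, a secreted BMP antagonist, rose by 2.90 ± 0.87 (FDR = 0.0315), MSX2, a homeobox gene, by 2.76 ± 0.76 (FDR = 0.0134), and SMAD9, which encodes a BMP-responsive SMAD, by 2.72 ± 0.27 (FDR = 2.97e-21). CBLN1, a secreted synaptic organizer, rose by 2.42 ± 0.15, COCH, an extracellular matrix protein of the inner ear, by 2.09 ± 0.17, MANEAL by 2.03 ± 0.16 and SMAD7 by 1.94 ± 0.16. The falls were smaller, with a median log2 fold change of -0.48 among lower genes against 0.97 among higher genes. WNT5A, a non-canonical WNT ligand, fell to -1.04 ± 0.25 (FDR = 0.00184) and F2RL1, a protease-activated receptor, to -1.01 ± 0.18 (FDR = 6.46e-06). BNIP3 (-0.95), the purinergic receptor P2RY1 (-0.93), the serotonin receptor HTR1D (-0.90), LMO3 (-0.89), LRRC55 (-0.89), TIAM2 (-0.85), BMP2 (-0.84) and MOB3C (-0.84) had the next largest falls among well-expressed genes, with FDR values between 4.96e-07 and 0.00354 in the authors' deposited table. With a required absolute log2 fold change of at least 1, the 499 called genes became 193, of which 180 were higher and 13 lower.

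BMP-SMAD1/5 targets again held the largest share of higher genes of the 16 lists at 4 h, with 13 of 20 members higher in the authors' deposited table and 0 lower (Fisher's exact test, adjusted p = 2.38e-16), or 16 higher and 1 lower when adjusted over the list alone. GATA3 rose by 5.29 ± 0.56, SMAD6 by 3.22 ± 0.26, DLX5 by 2.20 ± 0.66 and ID4 by 1.77 ± 0.15. MSX1 stood at 2.42 ± 1.30, ATOH8 at 0.87 ± 0.81, BMPER at 0.85 ± 0.43 and DLX2 at 2.38 ± 0.83 without passing. Among BMP pathway components, the receptors BMPR1A (0.64 ± 0.08) and BMPR2 (0.76 ± 0.17) and the antagonists NOG and BAMBI rose, 4 of 20 members (Fisher's exact test, adjusted p = 0.00495), while the ligand BMP2 fell. Adjusted over the list alone, 8 components were higher and 3 lower. BMP4 itself stood at 0.29 ± 0.29 and ACVR1 at 0.40 ± 0.16.

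Lineage regulators were among the genes called at 4 h too. In the primitive streak and mesoderm list, 6 of 22 tested members were higher in the authors' deposited table (Fisher's exact test, adjusted p = 5.58e-05), namely HAND1 (4.18 ± 0.62), FOXF1 (4.12 ± 1.23), CDX2 (2.90 ± 0.89), TBX3 (2.87 ± 0.42), GATA6 (2.55 ± 0.61) and WNT3 (1.85 ± 0.54). Adjusted over the list alone, 10 were higher and 1 lower. T stood at -0.80 ± 0.80, EOMES at 1.13 ± 0.37 (FDR = 0.0736), MIXL1 at 0.23 ± 0.94 and MESP2 at -1.40 ± 1.13, and these did not pass. In the trophectoderm and amnion list, 7 of 15 members were higher (Fisher's exact test, adjusted p = 1.88e-07) and the same number passed when adjusted over the list alone. These were GATA2, GATA3, HAND1, CDX2, TFAP2A (1.73 ± 0.50), TFAP2C (1.05 ± 0.18) and IGFBP3 (0.69 ± 0.19), while KRT8 stood at 0.24 ± 0.12, KRT18 at 0.14 ± 0.14, KRT7 at -0.37 ± 0.24 and ISL1 at 0.77 ± 0.53. Against the background of genes with at least 2511 counts, the adjusted p of Fisher's exact test for that list was 0.061. HHEX (1.75 ± 0.36) and GATA6 were the called members of the 14 tested in the definitive endoderm list (Fisher's exact test, adjusted p = 0.13), where 5 were higher and 1 lower when adjusted over the list alone. SOX17 stood at 1.72 ± 1.42 and FOXA2 at -2.82 ± 0.89 (FDR = 0.0522).

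Pluripotency genes were called in both directions at 4 h. SOX2 fell to -0.53 ± 0.14 (FDR = 0.0058), ZIC2 to -0.55 ± 0.14 and PRDM14 to -0.41 ± 0.12 in the authors' deposited table, and 4 of 24 pluripotency members were lower in all (Fisher's exact test, adjusted p = 0.000269). NANOG rose to 0.56 ± 0.17 (FDR = 0.0297) and KLF4 to 1.03 ± 0.27 (Fisher's exact test for higher members, adjusted p = 0.245). POU5F1 stood at 0.25 ± 0.14, LIN28A at -0.05 ± 0.08 and DNMT3B at -0.00 ± 0.10. The counts adjusted over the list alone were 4 lower and 2 higher. In the neural ectoderm list, POU3F1 (-0.78 ± 0.18) and SOX11 (-0.48 ± 0.12) fell, 2 of 16 members and 0 higher (Fisher's exact test, adjusted p = 0.0369). Adjusted over the list alone, 2 were lower and 1 higher. The median of the neural list was -0.46 at 4 h, below all 10000 random lists matched on totals, and 0.18 at 1 h, at percentile 99.5. Its members had a median implied SE of 0.63 at 4 h against 0.23 in matched lists, so its percentile at 4 h may partly reflect noisier values. Such percentiles were not particular to this list, since definitive endoderm was at 100, WNT at 0 and FGF/ERK at 0.04 at 4 h. PAX6 stood at -1.40 ± 0.79, SOX1 at -1.31 ± 1.02 and SOX3 at -0.44 ± 0.47 at 4 h without passing.

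Signalling genes moved in both directions at 4 h. In the WNT list, NOTUM, a secreted WNT inactivator, rose by 3.91 ± 0.46 (FDR = 8.87e-15), WNT3 by 1.85 ± 0.54 and TCF7 by 0.84 ± 0.15 in the authors' deposited table, while FZD7 fell to -0.82 ± 0.12 (FDR = 3.59e-10) and WNT5A fell as given above. These were 3 higher members (Fisher's exact test, adjusted p = 0.0479) and 2 lower members (adjusted p = 0.0533 in the same test) of 21, or 4 and 2 when adjusted over the list alone. The median of the list was -0.27 and its mean 0.08, so that they differ in sign. None of the 3 higher members had a total of 2511 counts or more, and against that background the adjusted p of Fisher's exact test was 1. AXIN2 stood at -0.64 ± 0.34, LEF1 at 0.42 ± 0.70 and SP5 at -1.13 ± 1.10. In the FGF/ERK list, FGF4 rose by 1.63 ± 0.33 and DUSP4 fell to -0.70 ± 0.20 of 16 members. HES1 (0.77 ± 0.20) was the only called member of 15 in the Notch/HES list, and SMAD7 of 15 in the NODAL/Activin list, where NODAL stood at -0.46 ± 0.78 and LEFTY1 at -0.44 ± 1.38. JUND (0.42 ± 0.12) and KLF4 rose among 26 immediate-early members. GADD45B (1.25 ± 0.25) rose and DDIT4 (-0.51 ± 0.16) fell among 16 stress and p53 members. For higher members of these lists, Fisher's exact test gave an adjusted p = 0.59 for FGF/ERK, Notch/HES, NODAL/Activin and stress, and 0.269 for the immediate-early list, and for lower members 0.281 for FGF/ERK and stress. Adjusted over the list alone, the higher and lower members were 1 and 2 for FGF/ERK, 1 and 0 for Notch/HES, 2 and 0 for NODAL/Activin, 6 and 4 for immediate-early, and 1 and 1 for stress.

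Epithelial, fibroblast and housekeeping genes had 0 called members at 4 h by the authors' FDR. At an unadjusted p-value under 0.05 in the authors' deposited table, 2 of 16 epithelial-mesenchymal members and 2 of 12 fibroblast members were higher, and 1 of 12 housekeeping members was lower. CDH1 stood at -0.02 ± 0.11, CDH2 at -0.39 ± 0.30, EPCAM at 0.02 ± 0.17 and VIM at 0.07 ± 0.33. The fibroblast and feeder markers, included because such cells can be present in stem cell cultures, had a median of -0.20 at 1 h and -0.16 at 4 h, at percentiles 0.06 and 0.96 of matched lists, with COL1A1 at -0.28 ± 0.14 and -0.28 ± 0.14. The housekeeping list had medians of 0.01 and 0.01, at percentiles 78.8 and 74.5.

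**Figure D1:**
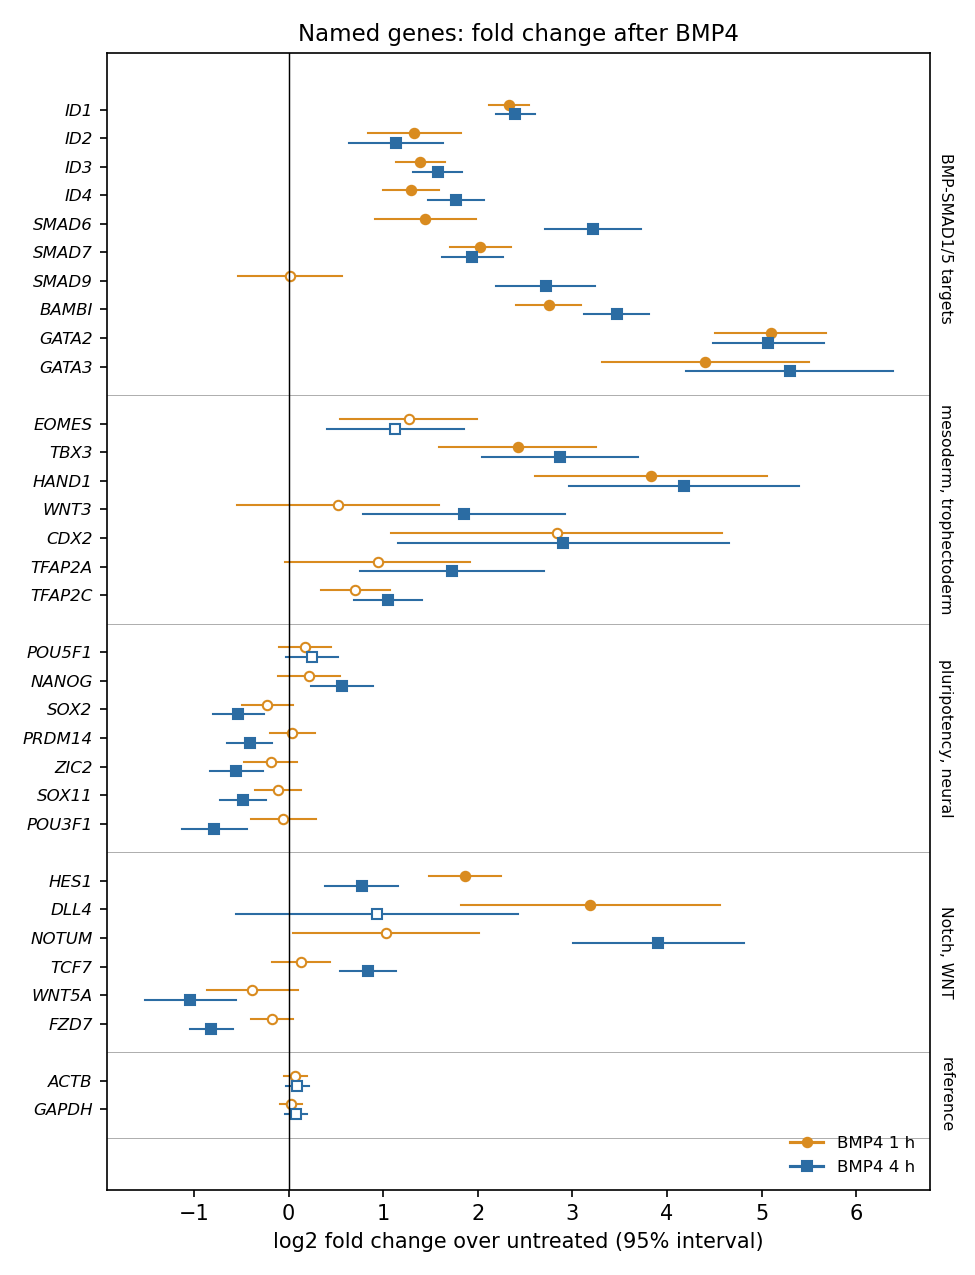
Log2 fold change over untreated cells (horizontal axis) of selected genes from the fixed lists after 1 h (orange circles) and 4 h (blue squares) of BMP4, from the authors' deposited table. Lines are 95% intervals from the implied SE, and filled symbols mark an FDR under 0.05. GATA2 lies at 5.10 and 5.07, SMAD9 at 0.01 and 2.72, and SOX2 at -0.22 and -0.53.

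Genes that had risen at 1 h were mostly still higher at 4 h. Of the 47 genes higher at 1 h in the authors' deposited table, 40 were also called higher at 4 h, where 0.977 would be shared by independent lists of these sizes among 17607 genes. Of the 6 lower genes, 3 were called lower at 4 h as well (expected 0.0453), namely RHOH, ZNF12 and C21orf91. No gene was called in opposite directions. Both comparisons use the same untreated libraries. The 100 simulations of unchanged groups against shared controls gave 0 shared calls, but they hold no effects and so do not show how far shared controls raise the overlap of changed genes. Across the 17607 genes, which are not independent replicates, the log2 fold changes at both times had a Pearson correlation of 0.651 and a covariance of 0.108, against 0.499 and 0.0811 in simulations with no effect. For the 9544 genes with totals of at least the median, the covariance was 0.0252 against 0.0106 simulated. The untreated libraries could not be split, so part of the excess of shared calls may come from the shared controls.

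The change from 1 h to 4 h was described from the difference between both log2 fold changes. Of 509 genes called at either time and with an FDR at both, 349 were higher at 4 h than at 1 h and 160 lower. Among the 509, 326 were called higher and 130 lower at 4 h and not at 1 h. The split therefore largely follows how the genes were chosen and does not by itself show a change between times. SMAD9 differed by 2.70, NOTUM by 2.88 and SMAD6 by 1.77, while HES1 differed by -1.09. With the required difference of at least 1, 91 genes were higher at 4 h and 12 lower. The conservative test of the difference, chosen after seeing the data, passed 64 genes at an FDR under 0.05, of which 57 were higher at 4 h and 7 lower, and the version without the shared controls passed 284. A gene called at 4 h and not at 1 h is therefore shown to differ between times only where it is among these.

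**Figure D2:**
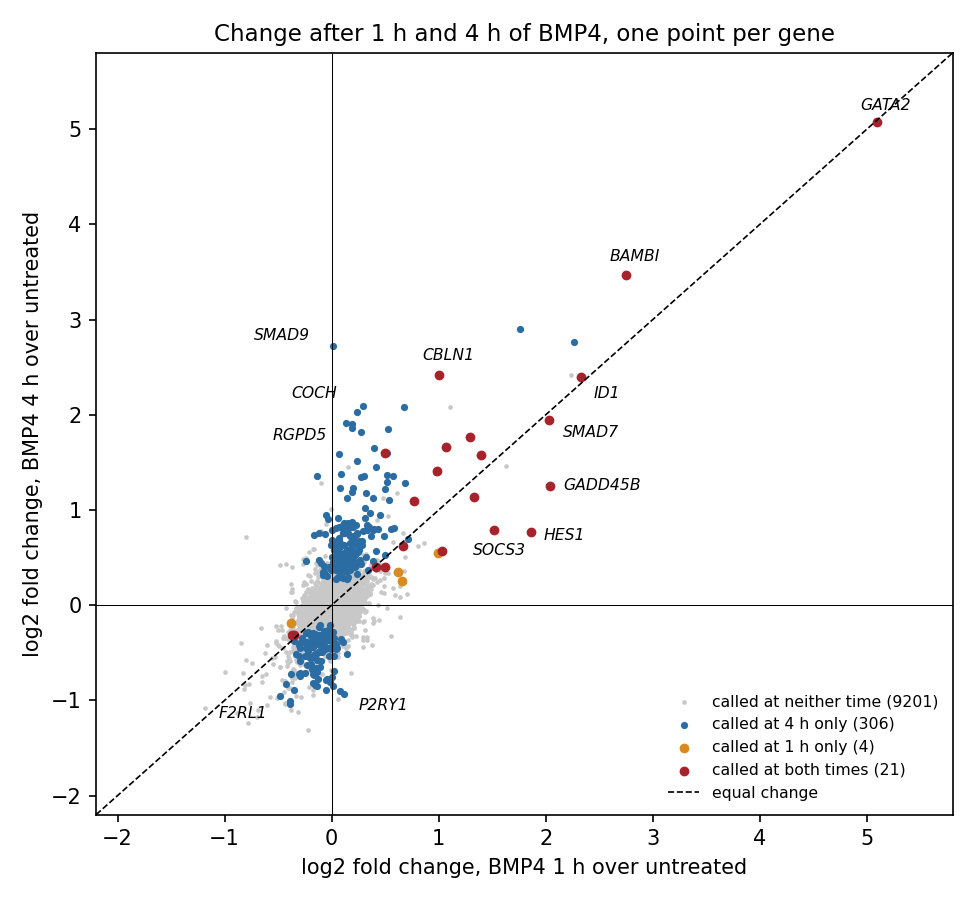
Log2 fold change after 1 h (horizontal axis) and 4 h (vertical axis) of BMP4 over untreated cells in the authors' deposited table, for the 9532 genes with a total of at least the median count, without XIST, TSIX and Y-linked genes. Points are genes, coloured by whether their FDR was under 0.05 at neither time (9201), at 4 h alone (306), at 1 h alone (4) or at both (21), and the dashed line marks equal change. GATA2, ID1 and SMAD7 lie near the line, COCH and SMAD9 above it and HES1 and GADD45B below it.

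The authors also deposited lists of changed genes. They hold 58 genes higher and 3 lower at 1 h, and 303 higher and 64 lower at 4 h, and each matches the genes with an FDR under 0.1 and a fold of at least 1.5 in the authors' deposited table. Of the listed genes, 44 and 3 at 1 h and 272 and 47 at 4 h were also called at an FDR under 0.05. Without the minimum fold, an FDR under 0.1 would give 63 higher and 11 lower genes at 1 h and 430 higher and 192 lower at 4 h.

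GATA2, GATA3 and TFAP2A overlap antisense transcripts that were called higher at 4 h in the authors' deposited table. GATA2-AS1 and GATA3-AS1 did not pass at 1 h (FDR = 0.319 and 0.166), and their totals of 58.7 and 127 counts were below the 3159 of GATA2 and 815 of GATA3. Whether strand was kept is not stated, so whether reads of these pairs were counted apart is unknown. Genes with few counts in untreated cells have imprecise folds, as in FOXF1, whose 95% interval at 1 h was 2.65 to 7.43.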

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

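The test of the difference between times and the RANBP2 test were chosen after the values were seen. The comparison of sequence shared between RGPD genes was set before its result was seen, although the rise of the RGPD genes themselves was known.

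The change relative to untreated cells differed between 4 h and 1 h of BMP4 for 64 genes by the conservative test of the difference at an FDR under 0.05, computed from the authors' deposited table. Among the genes named by the fixed rule, those higher at 4 h than at 1 h were NOTUM (log2 difference 2.88, FDR = 0.0087), SMAD9 (2.70, FDR = 8.31e-09), COCH (1.81, FDR = 1.56e-09), MANEAL (1.80, FDR = 1.77e-10), SMAD6 (1.77, FDR = 0.00132), CBLN1 (1.42, FDR = 2.86e-08) and BMPR1A (0.59, FDR = 5.20e-05). SMAD6, SMAD9 and BMPR1A encode parts of the BMP pathway, and NOTUM inactivates WNT ligands. Those lower at 4 h than at 1 h were HES1 (-1.09, FDR = 0.0236), P2RY1 (-1.04, FDR = 0.00205), HTR1D (-0.98, FDR = 0.00149) and FZD7 (-0.64, FDR = 0.0246). HES1 was called higher at both times and stood lower at 4 h, whereas P2RY1, HTR1D and FZD7 were not called at 1 h and fell by 4 h. GADD45B, SOCS3 and DLL4 had smaller folds at 4 h than at 1 h as well, and their differences did not pass this test. With the shared controls removed, the difference passed for SOCS3 (FDR = 0.000292) and not for GADD45B (FDR = 0.075) or DLL4 (FDR = 0.107).

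RGPD genes, a primate family of partial copies of the nuclear pore gene RANBP2, also differed between times. The log2 difference was 1.78 for RGPD8, 1.72 for RGPD6, 1.67 for RGPD5 and 1.16 for RGPD3, with FDR values of 4.58e-05, 0.000228, 8.14e-12 and 0.00169. At 4 h in the authors' deposited table, 6 of the 7 listed RGPD genes were higher than in untreated cells, from 0.59 ± 0.13 for RGPD4 to 1.91 ± 0.23 for RGPD8, and RGPD1 stood at -0.07 ± 0.32. RANBP2 itself stood at 0.08 ± 0.06 with an upper bound of 0.19 (95% interval). A fixed share of reads misplaced from RANBP2 could not raise the copies by more than RANBP2 rose, so these values argue against that source. Whether such a share changed between groups cannot be read from them. The bound of 0.5 for reads from RANBP2, which RANBP2 stayed below, was set after its values were seen. Reads shared between the copies may have spread a rise of fewer genes over the family: across the 6 copies other than RGPD5, the share of 50-base words found in RGPD5 transcripts, from 23.6% for RGPD1 to 98.6% for RGPD6, rose with the log2 fold change (Spearman rho = 0.886, exact one-sided permutation p = 0.0167). RGPD2 shared 24.9% of its words, close to RGPD1, yet stood at 0.86 ± 0.19. A rise of the most similar copies themselves would give the same correlation, so it cannot tell these explanations apart. Which copy rose cannot be read from these values, and a response of the family to BMP4 stays open and untested.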

How the results depend on the processing

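No paired analysis was possible because only the authors' comparison values were used and no values per library. For the same reason, leaving out replicates, other normalizations, other count tools, a fit of 6 libraries, pseudocounts, an estimated correlation within lists and other splits of the samples were not run, so whether any result rests on 1 library is unknown. The rule of the authors' lists, the adjustment at 1 h over fewer genes, the removal of repeated rows and RGPD genes and both tests of the difference between times were chosen after seeing the data. The 53 genes called at 1 h ranged from 40 to 61 and the 499 at 4 h from 350 to 493 under the other settings, except that an absolute log2 fold change of at least 1 left 193 at 4 h, with 180 of 366 higher and 13 of 133 lower genes. For 4 h against 1 h, 509 genes were described. A difference of at least 1 left 103, and the tests of the difference passed 64 (comparisons taken as independent) and 284 (shared controls removed). The 43 genes shared in direction between times ranged from 32 to 47. An FDR under 0.1 without minimum fold gave 11 lower genes at 1 h in place of 3 and 192 at 4 h in place of 64. With a list background of genes above the median total, 24 of 29 results of lists with called members kept their side of the threshold. Most of these 24 had passed neither before nor with this background. BMP-SMAD1/5 targets at 1 h and 4 h passed under both backgrounds (adjusted p = 1.88e-15 and 1.40e-10 here, Fisher's exact test). At 4 h, so did higher BMP pathway components (0.0326), lower pluripotency genes (0.00155) and lower neural ectoderm genes (0.0069 in the same test). All other list results that had passed and have a value here no longer passed. At 1 h the adjusted p of Fisher's exact test became 0.102 for trophectoderm and amnion, 0.108 for Notch/HES and 0.145 for immediate-early genes, and at 4 h 0.061 for trophectoderm and amnion and 1 for higher WNT genes. Fewer called members were left in each of these, and none of the higher WNT genes. Primitive streak and mesoderm had no members left at all, so that it gives no value. Its results, which had passed at both times, are not among the 29. Among the named genes, an FDR under 0.01 ended 8 calls at 1 h and 16 at 4 h, an absolute log2 fold change of at least 1 ended 7 and 30, and no filter ended 0 at 4 h. The rule of the authors' lists ended 4 and added 3 at 1 h and ended 10 and added 2 at 4 h, and the adjustment at 1 h over fewer genes added 2. Depth limits low genes most, since the median implied SE was 0.62 in the 25% of genes with the lowest totals.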

Other observations

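The families, the standard errors of lists, the neighbouring genes and the tests of each were chosen after values had been seen. For the neighbouring genes, the number of pairs was known when their tests were set.

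Genes were grouped by the letters that open their symbols, which gave 585 families with at least 5 tested members, and each was compared with all genes by Fisher's exact test in both directions and at both times (2340 tests). Only 5 tests passed an adjusted p under 0.05, and they concern the ID, GATA and RGPD families. Of 5 genes named ID, 4 were higher at 1 h and at 4 h (adjusted p = 4.74e-07 and 0.000462, Fisher's exact test). Of 7 genes named GATA, antisense transcripts included, 3 were higher at 1 h and 6 at 4 h (adjusted p = 0.000387 and 4.74e-07, Fisher's exact test). Besides GATA2, GATA3 and GATA6, this includes GATA5, a regulator of heart and endoderm, which rose by 2.77 ± 0.59 at 1 h and 4.23 ± 0.58 at 4 h in the authors' deposited table. The remaining called members were GATA2-AS1 and GATA3-AS1, which were called at 4 h alone and overlap their partners. Whether strand was kept, and so whether their reads were counted apart, is not stated.

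Genes higher at 4 h lay next to each other in the GRCh38.p14 annotation more often than expected. Among 361 higher genes that could be placed, 18 pairs were neighbours, against a mean of 7.62 when calls were permuted within bins of total counts (permutation p = 0.001, one-sided, 10000 permutations). Because the number of pairs was known when this test was set, its p-value describes the excess and cannot decide on chance placement. Without pairs that overlap, share a symbol root or hold an RGPD gene, 6 pairs were left, against 6.06 permuted (permutation p = 0.563). The excluded pairs may therefore account for the excess, which this test does not split by kind of pair. Among the excluded pairs are DLX5 with DLX6 and WNT3 with WNT9B, which do not overlap, and shared regulation of such pairs by BMP4 stays open and untested.

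Lineage genes had larger implied SEs than other genes with similar totals. The median of the neural ectoderm list at 4 h was 0.63 against 0.23 in matched random lists, above 100% of 10000 of them, which counting noise at a given total would not give. All 4 lineage lists lay above the central 95% of matched random lists, as a share of differentiating cells that varied between libraries could produce. However, 14 of the 16 lists did so, pluripotency included, while the fibroblast list lay at percentile 88.3 and the housekeeping list at 1.38. The data therefore leave open what widened these errors, with differentiating cells and a general variability of regulated genes among the possibilities. The libraries of each group also came from consecutive passages, an effect that these values cannot separate. Values per library would be needed to decide. No biological explanation tied to BMP4 was tested for this pattern.

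RPL30, which encodes a ribosomal protein, was higher at both times in the authors' deposited table, by 0.50 ± 0.12 (FDR = 0.0107) at 1 h and 0.40 ± 0.12 (FDR = 0.027) at 4 h. It was chosen after its values were seen. Both comparisons use the same untreated libraries, so the values at 1 h and 4 h are not independent.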
